A study of Homo sapiens with 18 samples.

How the data were processed

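RNA was measured in 18 libraries of SH-SY5Y cells, an established human neuroblastoma line, differentiated for 7 days with 10 µM all-trans retinoic acid and treated for 15 min with water or 1 of 5 opioid receptor ligands. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase I, libraries were made without strand information, and 150 bp paired reads were taken on an Illumina NovaSeq instrument. The deposited table gives raw read counts per Ensembl gene. Per the submitters' processing notes, FastQC, HISAT2, featureCounts and DESeq2 were used with the GRCh38 (hg38) build. Their versions, their settings and the gene annotation are not given in the sources used here. The 58735 gene IDs were exactly those of GENCODE 29, which was used for symbols, positions, exon lengths and GC content, and 41937 of them had a symbol. Because the counts carry no strand, reads of a gene and of an overlapping antisense gene cannot be separated, and reads of near-identical copies may have been split or dropped. Columns were matched to samples by their names, and no column was left unused.

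Totals ran from 21211449 to 33123855 counts per library, and no pair of libraries was identical. Library names end in a code, and code A stands for 0409, B for 1109 and C for 14.04. The TRV130 codes 10409 and 20409 were read as 0409. At the median, the 95% interval of a log2 fold change extended 0.495 to each side for 11980 genes with a mean of at least 10 CPM. The biological coefficient of variation was 0.309 with groups alone and 0.182 with the library code in the model.

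Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 (23231 genes), libraries were scaled by TMM, and the robust quasi-likelihood test was fitted to all 18 libraries with 1 mean per group, so that the groups shared an estimate of the spread. Standard errors were taken from the log2 fold change and its F statistic. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The comparisons were each compound with Control, each other compound with Morphine, any difference among the 6 groups, the mean of the 5 compounds with Control, and naloxone with the mean of the other 4.

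The gene lists, 31 in number, covered the genes of the study's title, opioid receptors and their signalling, early response genes, ion channels, neuronal identity, stress and metabolic pathways, and markers of cell types other than neuroblastoma. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 155 tests against Control and 124 against Morphine, and also with an estimated correlation and with fry. Lists with fewer than 3 tested members were to be left out. A list within a code was described by its mean log2 CPM (prior count 2) in a compound library minus that in the Control or Morphine library of the same code.

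Genes were named by a rule fixed before the data were examined: those that passed, or, where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p, given as values; the title genes, the opioid receptor genes, FOS, EGR1 and NR4A1 in every case; and up to 4 members of a list with the smallest p. Genes called by other tools alone, and genes set against the library code, were named after their values were seen. Some genes that met the rule are not reported. The comparisons, lists and most alternatives were likewise fixed before the data were examined: DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of the compared groups alone, the replicate number or the library code as a block, and each library left out in turn. Chosen after seeing the data were the fits without Control 1, Naloxone 1 and Naloxone 2, those with the code as a block and Control 1 or these 3 libraries left out, DESeq2 with the code, and limma voom with quality weights and the code. RLE and TMM scaling differed by at most 0.03 on the log2 scale.

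The tests were run on simulated counts of 23231 genes for morphine against Control. Changed genes, 100 at each fold size, and false calls were summed over the simulated tables of each setting. With spread that followed the library codes, the edgeR fit recovered 2% of 1.5-fold, 12% of 2-fold, 84% of 4-fold and 99% of 8-fold changes with 0 false calls. DESeq2 recovered 11%, 32%, 91% and 100% with 2 false calls. With spread that did not follow the codes it made 53 false calls and the edgeR fit 5. DESeq2 with the code in its model made 58 false calls where spread followed the codes and 69 where it did not. With the code as a block, edgeR recovered 28% of 1.5-fold and 58% of 2-fold changes where spread followed the codes, with 12 false calls. Where spread did not follow them, the block recovered 0% and 16% with 4 false calls, against 2% and 21% without the block. Camera found the moved list in 4 of 4 simulated tables and called 1 of 120 other list tests. Apart from code differences, which morphine and Control share alike, the simulated genes varied independently of one another. The count therefore does not show how often camera calls lists of correlated genes. Figures were drawn with matplotlib 3.10.9.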

Results

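RNA sequencing measured how the transcriptome of SH-SY5Y cells stood 15 min after the addition of an opioid receptor ligand. SH-SY5Y is an established human neuroblastoma line that takes on a neuron-like state with retinoic acid, and here it was differentiated for 7 days with 10 µM all-trans retinoic acid. The 18 libraries formed 6 groups of 3: water (Control), morphine at 193 nM, metamorphine at 169 nM, and TRV130, beta-endorphin and naloxone at 200 nM each. In the deposited table of raw read counts, 46594 genes had at least 1 count and 23231 were abundant enough to test. Total counts per library ran from 21211449 (Metamorphine 3) to 33123855 (TRV130 2), and the Control libraries held 25465814, 22455473 and 24126549. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

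The libraries grouped first by the code that ends each library name (called A, B and C here) and not by compound. Each code held 1 library of each group, except that TRV130 had 2 libraries of code A, 1 of code B and none of code C. The first principal component carried 40.4% of the variance and the second 24.0%. Control 1 stood apart on the second. It also held 20888 reads in 2077 of the 3647 protein-coding genes with a median count of 0 over the 18 libraries, against 276 to 1052 reads in 15 other libraries, 3074 in Naloxone 1 and 1495 in Naloxone 2. Reads of mitochondrially encoded RNA made up between 4.66% and 17.7% of a library.

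**Figure D1:**
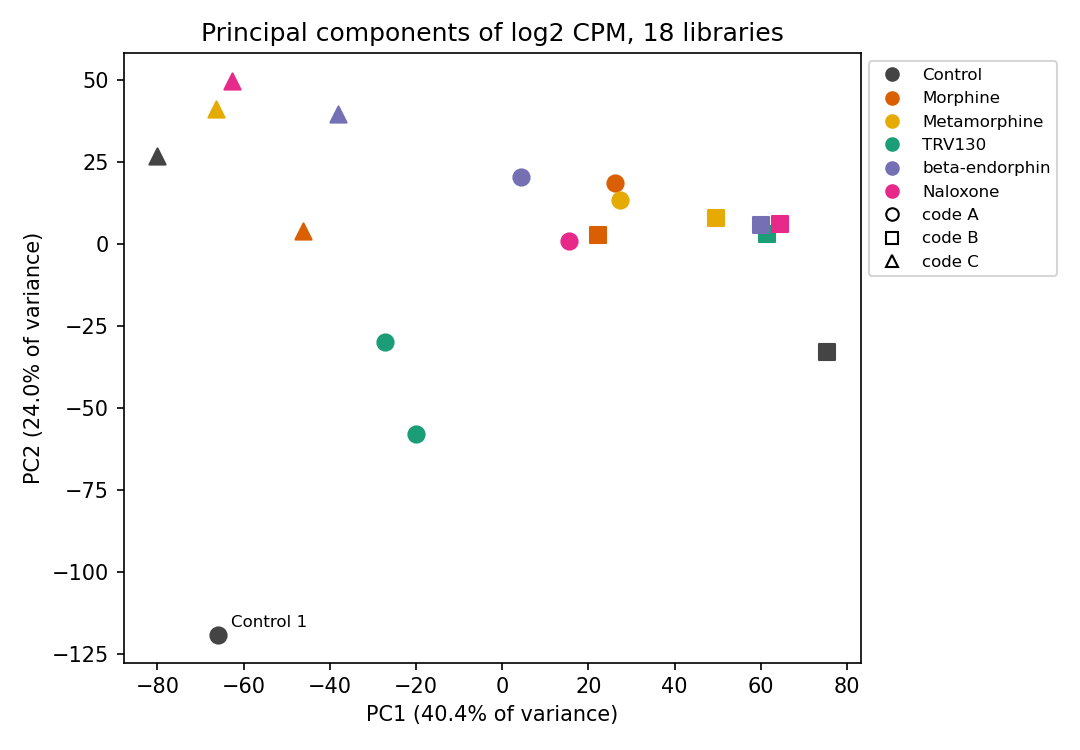
Principal components of log2 CPM, counts scaled to library size, for the 18 libraries, with colour giving the group and marker shape the library code; the axes carry 40.4% and 24.0% of the variance. The 5 libraries of code C lie at the left and those of code B at the right, and Control 1 has the lowest value on the second axis, at -119.3.

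The cells expressed 3 of the 4 opioid receptor genes. OPRD1, the delta receptor gene, averaged 88.8 CPM over all libraries, OPRL1, the nociceptin receptor gene, 16.7 CPM and OPRM1, the mu receptor gene at which morphine acts, 11.8 CPM. OPRK1, the kappa receptor gene, averaged 0.0466 CPM with 0 to 7 reads per library. Noradrenergic and neuronal transcripts were abundant: DBH, the enzyme that makes noradrenaline, averaged 1710 CPM, the transcription factor gene PHOX2A 1578 CPM, and the neuronal cytoskeletal genes TUBB3 and STMN2 651.1 and 476.8 CPM. TH, the rate-limiting enzyme of catecholamine synthesis, averaged 0.104 CPM. None of the tested receptor genes passed in any comparison with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and their log2 fold changes against Control ranged over the 5 compounds from 0.09 to 0.50 for OPRM1, from -0.34 to 0.03 for OPRD1 and from -0.02 to 0.21 for OPRL1. Control 1, 2 and 3 held 67.1, 185.3 and 43.6 CPM of OPRD1 and 5.78, 19.3 and 4.93 CPM of OPRM1. Control 2 had the highest value of both, which lowers the folds of both genes. Within codes A, B and C, OPRD1 lay below Control in 2 of 6, 5 of 5 and 0 of 4 compound libraries, and OPRM1 in 0 of 6, 3 of 5 and 0 of 4.

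The study's title names 4 genes in connection with opioid side effects: CACNA1F, a voltage-gated calcium channel subunit of the L type; RASAL1, a Ras GTPase-activating protein; GARIN4; and TRIM56, a ubiquitin ligase of the tripartite motif family. All 4 were near the detection limit in these cells. CACNA1F had 119, 4 and 0 reads in the 3 Control libraries, at most 3 reads in each of the 12 libraries of morphine, metamorphine, TRV130 and beta-endorphin, and 4, 5 and 0 in naloxone. RASAL1 had 55, 12 and 1 reads in Control, at most 4 in those 12 libraries, and 15, 7 and 0 in naloxone. TRIM56 had 103, 16 and 0 reads in Control, at most 7 in those 12, and 24, 5 and 6 in naloxone. GARIN4 had 9, 25 and 13 reads in Control, at most 2 in those 12, and 0, 12 and 5 in naloxone. GARIN4 was the only one of these 4 in which every Control library lay above each of those 12 libraries. In CPM the Control means were 1.85 ± 3.05 for CACNA1F, 1.02 ± 1.29 for RASAL1, 1.79 ± 2.51 for TRIM56 and 0.692 ± 0.368 for GARIN4 (SD, n = 3). For CACNA1F, RASAL1 and TRIM56 the SD was larger than the mean, and the highest count was in Control 1.

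On the GRCh38 build, CACNA1F (ENSG00000102001) lies on the minus strand of chromosome X from 49205063 to 49233371, and RASAL1 (ENSG00000111344) on the minus strand of chromosome 12 from 113098819 to 113136239. GARIN4 (ENSG00000162771) is a gene of 1 exon on the plus strand of chromosome 1 from 212624474 to 212626778, and TRIM56 (ENSG00000169871) lies on the plus strand of chromosome 7 from 101085439 to 101097967. An antisense gene, ENSG00000235862, overlaps GARIN4 and had the same 9, 25 and 13 reads in Control. The library was not stranded, so reads of the pair cannot be told apart and the values for GARIN4 are uncertain in that respect. CACNA1F was too low to be tested, which left 3 genes of the title in the tests. The study chose these genes on these samples, so their direction is not independent evidence.

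**Figure D2:**
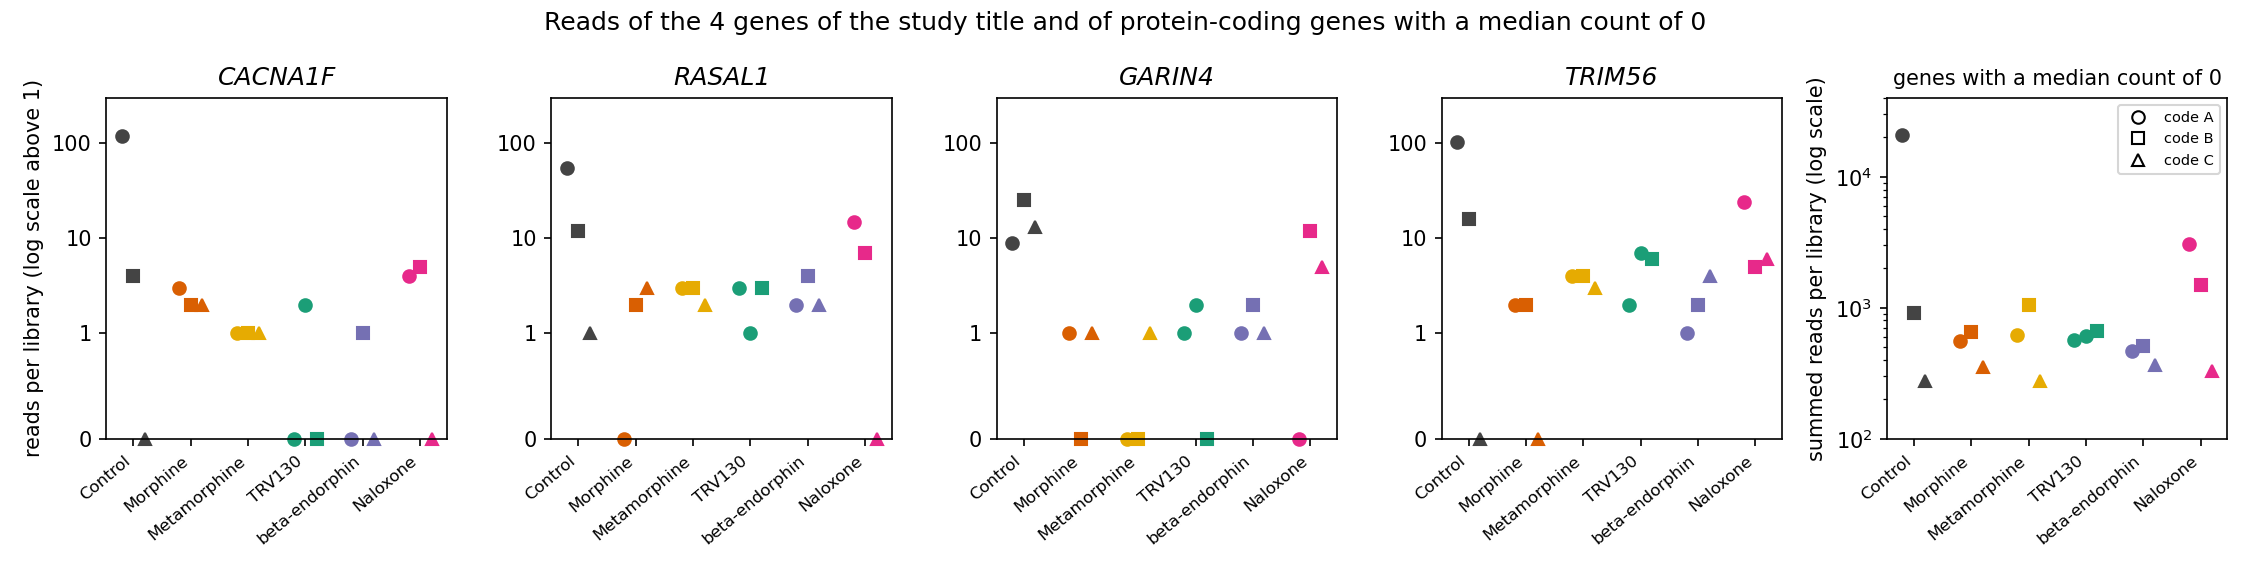
Reads per library of the 4 genes named in the study's title and, at the right, the summed reads of protein-coding genes with a median count of 0, with group on the x axis, colour by group and marker by library code. Control 1 holds 119 reads of CACNA1F, 103 of TRIM56, 55 of RASAL1 and 20888 reads of the genes with a median of 0.

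Morphine, a mu receptor agonist, was compared with water to ask what 15 min of exposure does to the transcriptome. The 3 title genes fell together, by a log2 fold change of -4.59 for GARIN4 (SE 1.17, 95% interval -7.06 to -2.12), -5.10 for TRIM56 (SE 1.33) and -3.99 for RASAL1 (SE 1.24; camera adjusted p = 2.57e-05, and adjusted p = 0.0428 with an estimated correlation). Without Control 1, TRIM56 stood at -2.80 and RASAL1 at -2.19. Ribosomal protein mRNAs fell as a group, with 78 of 78 members below Control and a median of -0.52 (RPL36 -0.83, RPS15 -0.59; adjusted p = 3.58e-09, and adjusted p = 0.892 with an estimated correlation). Nuclear-encoded respiratory chain mRNAs fell with 39 of 43 members lower and a median of -0.51 (ATP5F1D -0.62, NDUFS8 -0.65; adjusted p = 0.000106, and adjusted p = 0.914 with an estimated correlation). Neuronal genes rose slightly, with 21 of 33 members higher and a median of 0.08 (the intermediate filament gene INA 0.46, MAP2 0.49, DCX 0.55; adjusted p = 0.0319, and adjusted p = 0.725 with an estimated correlation). Genes of cAMP and protein kinase A signalling, the pathway that mu receptors inhibit, also rose (20 of 28 higher, median 0.19; PDE4B 0.39, ADCY5 0.37; adjusted p = 0.0319, and adjusted p = 0.556 with an estimated correlation).

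Markers of other cell types were lower in morphine than in Control. The immune cell markers fell (0 of 5 higher, median -1.15; CD68 -0.56, CD79A -1.25, or -0.60 for CD79A without Control 1; adjusted p = 0.00561, and adjusted p = 0.556 with an estimated correlation), as did the epithelial markers (11 of 12 lower, median -0.63; KRT8 -3.08, EPCAM -0.81; adjusted p = 0.0146, and adjusted p = 0.695 with an estimated correlation). The value for KRT8 rests on Control 1, which held 61 of its 71 reads in Control, and without that library it was -0.84. Most of the markers of these lists, 22 of 24 immune and 14 of 21 epithelial, averaged under 1 CPM in these cells. The early response genes did not pass as a list in morphine. FOS, a subunit of the AP-1 transcription factor, stood at -0.83 (SE 0.39, interval -1.66 to -0.01), NR4A1 at -0.63 and EGR1 at -0.22. FOS averaged 347.2 ± 156.8 CPM in Control and 194.7 ± 44.4 CPM in morphine (SD, n = 3). No single gene passed: the edgeR quasi-likelihood test called 0 of 23231 genes (944 at an unadjusted p under 0.05, smallest adjusted p 0.823), DESeq2 0, limma voom with quality weights and the library codes 0, and DESeq2 with the library codes 2. These were MYH16 (-2.44) and MYO1F (-2.87). The named genes with the smallest p were lower for MYO1F, an unconventional myosin (-2.96, SE 0.66), LSR, the lipolysis-stimulated lipoprotein receptor (-1.10, SE 0.26), ZNF442 (-1.24) and NR1I2 (-5.40, or -3.90 without Control 1). Those on the higher side were the integrin gene ITGA6 (1.06, SE 0.29), the neuronal adhesion gene CNTN1 (0.71, SE 0.21), GGTA2P (2.77), RNU6-322P (3.49) and RPL7AP49 (4.34). The last 3 are pseudogenes or copies of repeated genes, so their reads are uncertain. Adjusted over the list alone, 3 of 3 title genes and 1 member of the TRIM family (TRIM56) passed in morphine, and 0 members of each other list, against 0 over all genes. TRIM56 is itself a title gene, and the study chose the title genes on these samples. Their passing over the list alone, here and in the other compounds, is therefore not independent evidence.

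Morphine minus Control, within codes A, B and C, was -4.05, -2.86 and -0.60 for the mean log2 CPM of the title genes, -1.24, 0.38 and -0.41 for the ribosomal list, -0.94, 0.31 and -0.36 for the respiratory chain and -1.44, -0.26 and 0.36 for the epithelial markers. For the immune markers it was -1.63, -0.78 and 0.11, for neuronal genes 0.07, 0.24 and 0.09 and for cAMP signalling 0.36, 0.06 and 0.14. Of the 7 list calls, 2 (title genes and ribosomal proteins) held with each library left out in turn. Calls that ended without Control 1 were the epithelial (adjusted p = 0.645), respiratory chain (0.0692) and cAMP (0.0527) lists. Without Control 2 they were the neuronal (0.538), immune (0.0793) and cAMP (0.0946) lists, and without Control 3 the respiratory chain (0.333), cAMP (0.0843) and neuronal (0.0571) lists. The cAMP list also ended without Morphine 1 (0.0628) or Morphine 3 (0.0605), and the neuronal list without Morphine 3 (0.066).

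Metamorphine, at 169 nM, was compared with water in the same way. The title genes fell, with GARIN4 at -5.27 (SE 1.27), TRIM56 at -3.59 (SE 1.18) and RASAL1 at -3.23 (SE 1.17; camera adjusted p = 0.00277, and adjusted p = 0.174 with an estimated correlation). All 13 mRNAs encoded by the mitochondrial genome lay lower, with a median of -0.73 (MT-ND3 -1.07, SE 0.35, MT-CO2 -0.87, SE 0.40; adjusted p = 0.000136, and adjusted p = 0.842 with an estimated correlation). Ribosomal protein mRNAs fell (78 of 78 lower, median -0.50; RPL36 -0.83, RPS15 -0.65; adjusted p = 2.22e-07), and so did the respiratory chain (37 of 43 lower, median -0.48; ATP5F1D -0.74, NDUFA13 -0.81; adjusted p = 0.000702), with adjusted p = 0.914 for both with an estimated correlation. The epithelial markers fell (12 of 12 lower, median -0.54; EPCAM -1.28, KRT8 -2.83, or -0.58 for KRT8 without Control 1; adjusted p = 0.00277, and adjusted p = 0.577 with an estimated correlation), and the immune markers too (5 of 5 lower, median -0.87; CD14 -0.87, CD79A -1.71, or -1.05 for CD79A without Control 1; adjusted p = 0.00419, and adjusted p = 0.556 with an estimated correlation).

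FOS stood at -0.83 (SE 0.39), NR4A1 at -0.61 and EGR1 at -0.16 in metamorphine. The edgeR quasi-likelihood test called 0 of 23231 genes (1820 at an unadjusted p under 0.05, smallest adjusted p 0.595), and DESeq2, limma voom with quality weights and the library codes, and DESeq2 with the codes each called 0. Among named genes with the smallest p, the higher ones were ITGA6 (1.17, SE 0.29), the dynein heavy chain gene DNAH7 (1.59, SE 0.44), MAP3K1, a kinase upstream of the MAP kinases (0.59, SE 0.17), PUS7L (0.67) and the U6 copy RNU6-146P (2.18, uncertain). The lower ones, beside GARIN4, were the troponin gene TNNT2 (-2.12, SE 0.53), MEI1 (-3.95, or -2.43 without Control 1), RAB44 (-6.58) and the pseudogene IRS3P (-2.97). Adjusted over the list alone, 3 of 3 title genes, 3 immune markers and 1 epithelial marker passed, and 0 members of each other list, against 0 over all genes. Within codes A, B and C the mean difference was -3.70, -2.43 and -0.11 for the title genes, -0.60, -1.08 and -0.08 for the mitochondrial list, -1.33, 0.11 and -0.15 for the ribosomal list and -0.995, 0.11 and -0.19 for the respiratory chain. For the immune markers it was -1.52, -0.90 and -0.14 and for the epithelial markers -1.52, -0.37 and -0.01. Of the 6 calls, 1 (the title genes) held with each library left out. The epithelial (adjusted p = 0.0846) and respiratory chain (0.0816) calls ended without Control 1 and the mitochondrial (0.155) and immune (0.0541) calls without Control 2. The ribosomal (0.0636) and respiratory chain (0.392) calls ended without Control 3, and the respiratory chain call also without Metamorphine 2 (0.0983).

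TRV130 at 200 nM differed from water in 11 of 31 lists, with 4 higher and 7 lower. It has 2 libraries of code A and none of code C, while Control has 1 of each code, so its folds carry differences between codes as well as the compound. The early response list fell (21 of 30 members lower, median -0.16; FOS -1.03, SE 0.39, FOSB -1.36, SE 0.57, KLF2 -1.13, SE 0.46; adjusted p = 0.00277, and adjusted p = 0.556 with an estimated correlation). Without Control 2, which had the most FOSB, FOSB stood at -0.46. Genes of sterol synthesis rose (20 of 22 higher, median 0.25; INSIG1 0.48, SQLE 0.49; adjusted p = 1.39e-05, and adjusted p = 0.819 with an estimated correlation). Mitochondrially encoded mRNAs rose (12 of 13 higher, median 0.45; MT-ND4L 0.80, MT-ND5 0.74; adjusted p = 7.83e-05, and adjusted p = 0.819 with an estimated correlation). The title genes fell, with GARIN4 at -4.11 (SE 1.11), RASAL1 at -3.53 (SE 1.19) and TRIM56 at -3.31 (SE 1.14; adjusted p = 1.13e-05, and adjusted p = 0.0428 with an estimated correlation).

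Noradrenergic genes rose with TRV130 (21 of 26 higher, median 0.16; the nicotinic receptor gene CHRNA3 0.31, TFAP2B 0.31; adjusted p = 0.00531, and adjusted p = 0.556 with an estimated correlation), as did neuronal genes (24 of 33 higher, median 0.08; NRXN2 0.40, SYN1 0.47; adjusted p = 0.0259, and adjusted p = 0.695 with an estimated correlation). Ribosomal protein mRNAs fell (78 of 78 lower, median -0.46; RPL23A -0.55; adjusted p = 3.18e-12, and adjusted p = 0.886 with an estimated correlation), with the respiratory chain (43 of 43 lower, median -0.33; ATP5F1B -0.27; adjusted p = 1.39e-05, and adjusted p = 0.892 with an estimated correlation) and the replication-dependent histone genes (19 of 22 lower, median -0.37; H2AC17 -1.24, H2BC11 -0.78; adjusted p = 0.00547, and adjusted p = 0.886 with an estimated correlation). Within codes A and B the histone difference was only -0.11 and 0.04, and TRV130 has no library of code C. Schwann cell and glial markers fell (9 of 12 lower, median -0.20; ERBB3 -1.67, or -0.56 without Control 1, and SOX10 -1.75, or -0.82 without Control 2; adjusted p = 0.0335, and adjusted p = 0.556 with an estimated correlation), and the epithelial markers fell as well (9 of 12 lower, median -0.25; CLDN7 -2.66, KRT8 -2.54, or -0.30 for KRT8 without Control 1; adjusted p = 0.0319, and adjusted p = 0.765 with an estimated correlation).

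With TRV130 the edgeR quasi-likelihood test called 0 of 23231 genes (430 at an unadjusted p under 0.05, smallest adjusted p 1.00). DESeq2 called 1, the long noncoding RNA LINC02983 (-1.07, adjusted p = 0.0316), limma voom with quality weights and the codes 1, MYH16 (-2.71, adjusted p = 0.0208), and DESeq2 with the codes 4. The named genes with the smallest p were the noncoding RNAs FZD10-AS1 (-3.42, SE 0.71), LINC00942 (-2.98, SE 0.62) and LINC02983 (-1.05, SE 0.22), the pseudogene PPP5D1P (-1.99) and BATF3, a transcription factor of the AP-1 family (-1.55, SE 0.39). On the higher side were RGPD5 (1.68, SE 0.47), a member of a family of near-identical copies and so uncertain, CNTN1 (0.67, SE 0.21), RNU6-146P (1.62), SPART-AS1 (1.21) and LINC01376 (1.14). Adjusted over the list alone, 3 of 3 title genes passed and 0 members of each other list, against 0 over all genes.

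TRV130 had no library of code C, so its within-code values rest on codes A and B. They were -3.49 and -2.41 for the title genes, 0.05 and -0.38 for the early response list, 0.04 and 0.23 for sterol synthesis, 0.50 and -0.69 for the mitochondrial list, 0.18 and 0.11 for noradrenergic genes, -0.60 and -0.17 for ribosomal proteins, -0.41 and -0.09 for the respiratory chain, 0.06 and 0.16 for neuronal genes, -0.69 and -0.35 for glial markers and -1.15 and -0.14 for epithelial markers. The early response, mitochondrial and histone lists had opposite signs in the 2 codes. Of the 11 calls, 1 (the title genes) held with each library left out. Without Control 1 the glial (adjusted p = 0.471), ribosomal (0.0678) and respiratory chain (0.42) calls ended and the epithelial list changed direction (0.699). Without Control 2 the early response (0.2), neuronal (0.64), noradrenergic (0.323), sterol (0.409), glial (0.14) and epithelial (0.0793) calls ended, while those that ended without Control 3 were the early response (0.211), mitochondrial (0.845), histone (0.699) and respiratory chain (0.23) calls. Leaving out TRV130 1 ended the mitochondrial (0.108), histone (0.0897) and glial (0.0561) calls, and leaving out TRV130 2 the neuronal (0.297), noradrenergic (0.203), glial (0.15) and epithelial (0.128) calls. Without TRV130 3 the ribosomal (0.194), respiratory chain (0.684), glial (0.097) and epithelial (0.232) calls ended, and without Naloxone 3 the epithelial call (0.0534).

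**Figure D3:**
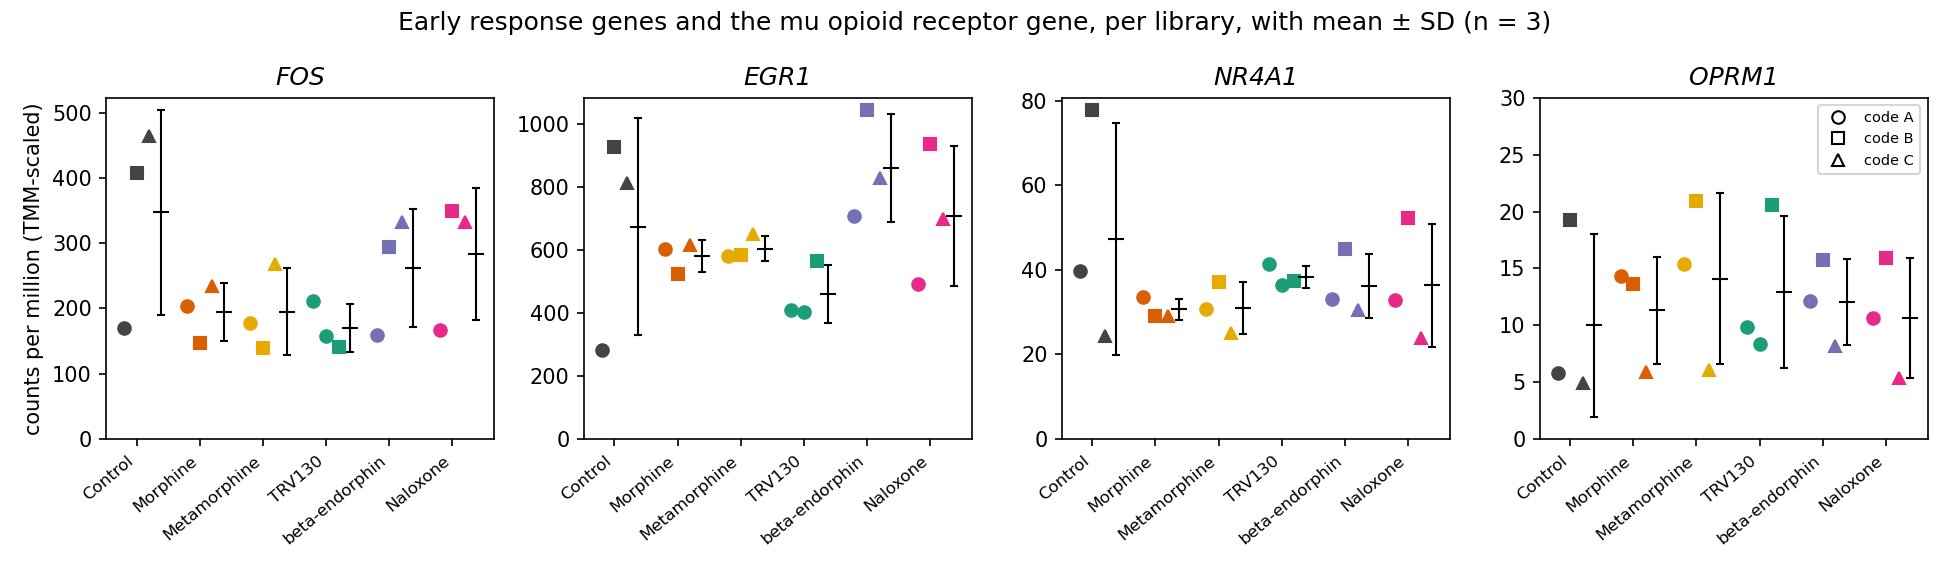
FOS, EGR1, NR4A1 and OPRM1 in CPM scaled by TMM factors, per library, with the mean and SD of each group at its right (n = 3), colour by group and marker by library code. FOS was 169.2, 407.6 and 464.8 CPM in the 3 Control libraries, and TRV130 averaged 169.5 CPM with an SD of 36.7.

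FOS was compared within the codes as well. In code A it stood at 169.2 CPM in Control and between 156.9 and 210.9 CPM in the 6 compound libraries, 3 of which lay below Control. In code B the Control value was 407.6 CPM and all 5 compound libraries lay below it, from 138.5 to 349.9 CPM. In code C it was 464.8 CPM with all 4 compound libraries below it, from 234.4 to 332.2 CPM. EGR1 in code A was lower in Control (281.9 CPM) than in all 6 compound libraries (402.7 to 705.2 CPM), while 3 of 5 lay below Control in code B and 3 of 4 in code C. NR4A1 stood at 39.8, 77.8 and 24.3 CPM in the Controls of codes A, B and C. It lay below them in 5 of 6, 5 of 5 and 1 of 4 compound libraries, so its lower values did not hold in code C. None of these genes passed in any compound.

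Beta-endorphin, the endogenous peptide agonist of mu and delta receptors, was applied at 200 nM. Ribosomal protein mRNAs fell (78 of 78 lower, median -0.62; RPL36 -0.90, RPL29 -0.86; adjusted p = 5.3e-10, and adjusted p = 0.889 with an estimated correlation), together with the respiratory chain (36 of 43 lower, median -0.54; ATP5F1D -0.77, NDUFS8 -0.81; adjusted p = 0.000185, and adjusted p = 0.914 with an estimated correlation). The 13 mitochondrially encoded mRNAs all lay lower (median -0.61; MT-ND3 -0.93, SE 0.35; adjusted p = 0.00363, and adjusted p = 0.886 with an estimated correlation). The title genes fell, with TRIM56 at -4.22 (SE 1.24), GARIN4 at -3.62 (SE 1.07) and RASAL1 at -3.23 (SE 1.17; adjusted p = 0.00547, and adjusted p = 0.218 with an estimated correlation). Ras GTPase-activating proteins rose as a list, 11 of 12 higher with a median of 0.31 (NF1 0.53, SE 0.27, IQGAP1 0.52, SE 0.22; adjusted p = 0.0319, and adjusted p = 0.886 with an estimated correlation), although RASAL1, which is also in this list, brought its mean to 0.015 on the log2 scale.

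Genes of cAMP and protein kinase A signalling rose with beta-endorphin (20 of 28 higher, median 0.27; PRKAR2A, a regulatory subunit of the kinase, 0.50, ADCY1 0.86; adjusted p = 0.0498, and adjusted p = 0.556 with an estimated correlation). The epithelial markers fell (11 of 12 lower, median -0.76; EPCAM -1.27, CLDN3 -1.91; adjusted p = 0.00547, and adjusted p = 0.654 with an estimated correlation), and the immune markers fell (5 of 5 lower, median -0.87; CD79A -1.42, or -0.78 without Control 1, CD14 -0.61; adjusted p = 0.0146, and adjusted p = 0.63 with an estimated correlation). FOS stood at -0.41 (SE 0.39), NR4A1 at -0.39, EGR1 at 0.35 and EGR2 at 0.81. With beta-endorphin the edgeR quasi-likelihood test called 0 of 23231 genes (2198 at an unadjusted p under 0.05, smallest adjusted p 0.513), DESeq2 1 (a transcript without a symbol, -0.60, adjusted p = 0.0285), limma voom with quality weights and the codes 22, all lower, and DESeq2 with the codes 14, of which 3 were higher. Named genes with the smallest p were LPAR6, a lysophosphatidic acid receptor (-2.17, SE 0.49), LSR (-1.12, SE 0.26), the sialyltransferase gene ST6GALNAC2 (-2.53), the hydroxysteroid dehydrogenase gene HSD17B14 (-0.90, SE 0.23) and the pseudogene THA1P (-1.46). On the higher side were CNTN1 (0.86, SE 0.21), ITGA6 (1.16, SE 0.29), PSD3 (0.79, SE 0.21), and, with uncertain reads, RPL7AP49 (4.67) and RNU6-146P (1.95). Adjusted over the list alone, 3 of 3 title genes and 1 epithelial marker passed, and 0 members of each other list, against 0 over all genes.

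Beta-endorphin minus Control, within codes A, B and C, was -3.90, -2.17 and -0.14 for the title genes, -1.06, -0.30 and -0.37 for ribosomal proteins, -0.75, -0.18 and -0.32 for the respiratory chain and -1.16, -0.62 and 0.38 for the mitochondrial list. For the immune markers it was -1.76, -0.59 and -0.13, for the epithelial markers -1.40, -0.29 and -0.06, for cAMP signalling 0.32, 0.07 and 0.18 and for Ras GTPase-activating proteins 0.34, 0.00 and 0.20. Of the 8 calls, 1 (the ribosomal proteins) held with each library left out. The epithelial (adjusted p = 0.198) and Ras GTPase-activating (0.132) calls ended without Control 1, the title (0.0701), immune (0.0992) and mitochondrial (0.348) calls without Control 2, and the Ras GTPase-activating (0.294) and respiratory chain (0.23) calls without Control 3. Leaving out beta-endorphin 1 ended the immune (0.0625) and mitochondrial (0.0678) calls and leaving out beta-endorphin 2 the Ras GTPase-activating (0.22) and respiratory chain (0.22) calls. The cAMP call ended in 11 of 18 such fits, among them those without Control 1 (0.0564), 2 (0.103) or 3 (0.103) and without any 1 library of TRV130 or beta-endorphin, with adjusted p from 0.0511 to 0.103.

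Naloxone, an antagonist of opioid receptors, was given alone at 200 nM. Ribosomal protein mRNAs fell (78 of 78 lower, median -0.56; RPL36 -0.88, RPS15 -0.69; adjusted p = 7.71e-10, and adjusted p = 0.892 with an estimated correlation), as did the respiratory chain (39 of 43 lower, median -0.51; ATP5F1D -0.76, NDUFS8 -0.70; adjusted p = 0.00046, and adjusted p = 0.914 with an estimated correlation). All 13 mitochondrially encoded mRNAs lay lower (median -0.51; MT-ND3 -0.84, SE 0.35; adjusted p = 0.00547, and adjusted p = 0.889 with an estimated correlation). The epithelial markers fell (12 of 12 lower, median -0.72; EPCAM -1.27, CLDN3 -1.67; adjusted p = 0.00715, and adjusted p = 0.654 with an estimated correlation), and the immune markers fell (5 of 5 lower, median -0.81; CD14 -0.81, CD68 -0.68; adjusted p = 0.00363, and adjusted p = 0.556 with an estimated correlation). The title genes did not pass in naloxone: GARIN4 stood at -1.75 (SE 0.91, interval -3.68 to 0.18), TRIM56 at -2.15 (SE 1.06) and RASAL1 at -1.99 (SE 1.06; camera adjusted p = 0.0893), with 0 of 3 adjusted over the list alone.

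FOS stood at -0.30 (SE 0.39), NR4A1 at -0.38 and EGR1 at 0.07 in naloxone. Here the edgeR quasi-likelihood test called 0 of 23231 genes (1545 at an unadjusted p under 0.05, smallest adjusted p 0.655), DESeq2 1 (a processed pseudogene without a symbol, -2.02, adjusted p = 0.0413), and limma voom with quality weights and the codes, and DESeq2 with the codes, 0 each. Named genes with the smallest p were higher for ITGA6 (1.27, SE 0.29), CNTN1 (0.84, SE 0.21), LRP12 (0.64, SE 0.18), RNU6-146P (1.76) and RPL7AP49 (4.66), and lower for the lens crystallin gene CRYGS (-1.03, SE 0.27), the small nuclear RNAs SCARNA2 (-2.71) and RN7SK (-2.83) and the pseudogene MED28P8 (-4.15). Control 2 held 494 of the 646 reads of RN7SK in Control, and without it RN7SK stood at -1.31. Adjusted over the list alone, 2 immune markers and 1 epithelial marker passed, and 0 members of each other list, against 0 over all genes. Naloxone minus Control, within codes A, B and C, was -1.19, -0.37 and -0.13 for ribosomal proteins, -0.88, -0.20 and -0.10 for the respiratory chain and -0.40, -0.58 and -0.41 for the mitochondrial list. For the immune markers it was -1.19, -0.70 and -0.84 and for the epithelial markers -1.2, -0.16 and -0.19.

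Of the 5 naloxone calls, 1 (the ribosomal proteins) held with each library left out. The epithelial (adjusted p = 0.327) and respiratory chain (0.0713) calls ended without Control 1, and the immune (0.0541) and mitochondrial (0.424) calls without Control 2. The respiratory chain call also ended without Control 3 (0.353) or Naloxone 2 (0.511), and the immune (0.0975), epithelial (0.115) and mitochondrial (0.695) calls without Naloxone 3.

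**Figure D4:**
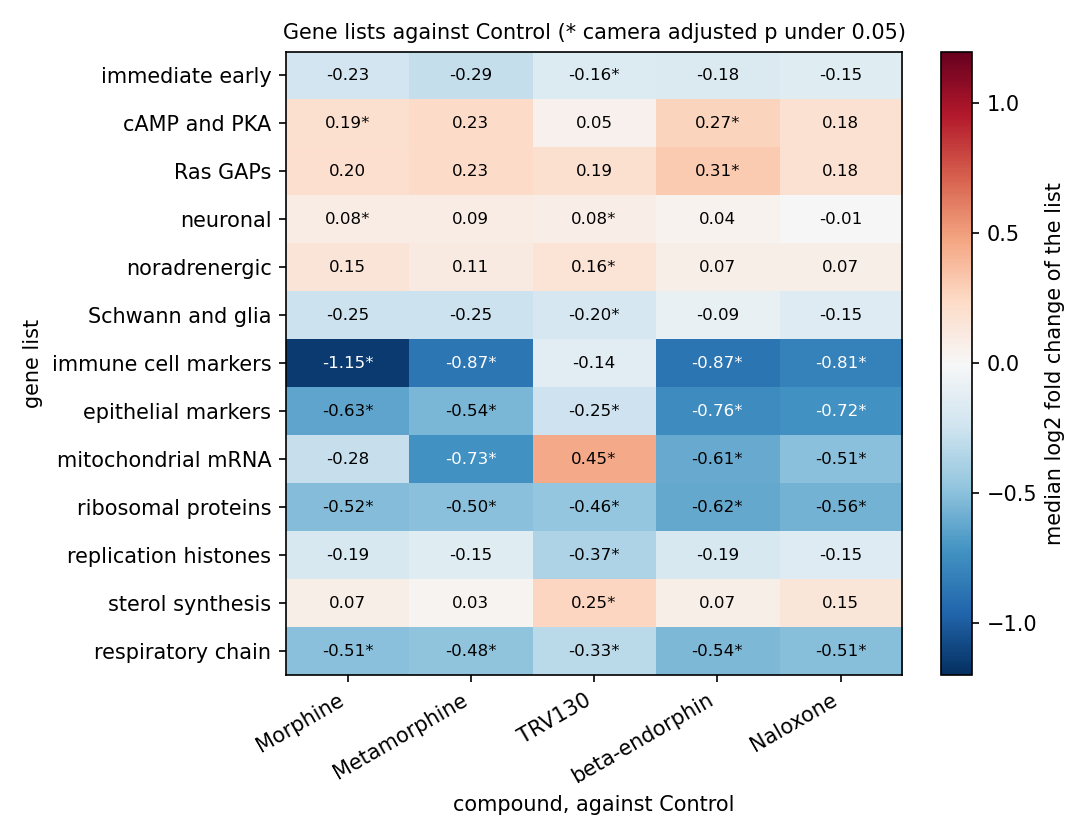
Median log2 fold change against Control of the 13 gene lists other than the title genes that passed in at least 1 of the 5 comparisons, with compounds in columns and an asterisk where the camera adjusted p was under 0.05. Ribosomal proteins run from -0.62 to -0.46 over the 5 compounds, and the mitochondrial mRNA list is 0.45 in TRV130 and from -0.73 to -0.28 in the other 4.

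Over the 5 comparisons with Control, 37 of 155 list tests passed with camera at its preset correlation, 2 with an estimated correlation (the title genes in morphine and TRV130) and 0 with fry. The study chose the title genes on these samples, so those 2 calls are not independent evidence. Of the 31 lists, 17 passed in none of the 5. The same 3 Control libraries entered each comparison, so a list that moves in those libraries moves in all 5 comparisons. Without Control 1, 23 of the 37 calls held and 31 others arose. The folds of TRIM56 and RASAL1, but not of GARIN4, were also smaller without Control 1: TRIM56 stood at -1.26 in metamorphine, -1.0 in TRV130 and -1.91 in beta-endorphin, and RASAL1 at -1.42, -1.74 and -1.43. ATP5F1D of the respiratory chain stood at -0.26 in morphine, -0.36 in metamorphine and -0.37 in naloxone without it. Some higher genes did not rest on Control 1 alone: ITGA6 had 18 to 40 reads in the Control libraries and 44 to 92 in the 15 compound libraries, and DNAH7 4 to 16 against 19 to 52. MAP3K1 likewise had 652 to 919 reads in Control and 1071 to 1727 with the compounds.

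The direct comparison of metamorphine with morphine asked whether these opioids, at 169 and 193 nM, gave different responses. Mitochondrially encoded mRNAs were lower with metamorphine (13 of 13, median -0.44; adjusted p = 2.8e-09, and adjusted p = 0.987 with an estimated correlation). FOS differed by 0.00 (interval -0.82 to 0.82), EGR1 by 0.06 (interval -0.67 to 0.78), GARIN4 by -0.67 (interval -4.21 to 2.86) and TRIM56 by 1.52 (interval -1.57 to 4.60). The genes with the smallest p included CSAG2 (2.53, SE 0.79, or 1.32 without Metamorphine 3), CDC42EP5 (-1.79, SE 0.56), STARD8 (1.19, SE 0.43) and the pseudogene ZNG1DP (-1.37, SE 0.38). Between these 2 opioids the edgeR quasi-likelihood test called 0 of 23231 genes (75 at an unadjusted p under 0.05), as did DESeq2, limma voom with quality weights and the codes, and DESeq2 with the codes. Of 11980 genes with a mean of at least 10 CPM, 92.1% had a 95% interval of the difference within 1 log2 unit of 0. Larger differences lay outside the interval of each such gene taken alone and stay open for the rest. The intervals are not adjusted over genes, so some may miss the true difference. The mitochondrial call held with each library left out (adjusted p up to 0.0424). Within codes A, B and C the differences in mean log2 CPM were -0.10, -0.46 and -0.88.

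TRV130 at 200 nM differed from morphine at 193 nM in mitochondrially encoded mRNAs, which were higher in TRV130 (13 of 13, median 0.73; adjusted p = 1.53e-08, and adjusted p = 0.987 with an estimated correlation). Morphine has a library of each code and TRV130 none of code C, so these folds and their p carry differences between codes as well. Sterol synthesis genes were higher (18 of 22, median 0.34; adjusted p = 0.00126, and adjusted p = 0.993 with an estimated correlation), and so were the immune markers (5 of 5, median 0.51; adjusted p = 0.0284, and adjusted p = 0.987 with an estimated correlation). FOS differed by -0.20 (interval -1.02 to 0.62), EGR1 by -0.34 (interval -1.06 to 0.39) and GARIN4 by 0.48 (interval -2.58 to 3.54). RGPD5 stood at 1.97 (interval 0.98 to 2.96, uncertain as above), LINC00942 at -2.22 (SE 0.63) and the coenzyme Q gene COQ4 at 0.47 (SE 0.16). Between TRV130 and morphine the edgeR quasi-likelihood test called 0 of 23231 genes (275 at an unadjusted p under 0.05), as did the other 3 fits, DESeq2, limma voom with quality weights and the codes, and DESeq2 with the codes. The interval lay within 1 log2 unit of 0 for 84.5% of the 11980 genes. The sterol call ended without Morphine 3 (adjusted p = 0.123) or TRV130 2 (0.265) and the immune call without Morphine 1 (0.0877), TRV130 1 (0.0781) or TRV130 3 (0.0759). Within codes A and B the differences were 1.00 and -0.07 for the mitochondrial list, 0.17 and -0.03 for sterol synthesis and 0.82 and 0.37 for the immune markers. The first 2 did not hold in code B.

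Beta-endorphin at 200 nM gave lower mitochondrially encoded mRNAs than morphine at 193 nM (13 of 13, median -0.34; adjusted p = 5.59e-05) and higher cell cycle genes (29 of 34, median 0.12; adjusted p = 0.007), with slightly lower ribosomal protein mRNAs (68 of 78, median -0.10; adjusted p = 0.0288). For each of these the adjusted p = 0.993 with an estimated correlation. EGR1 stood at 0.57 (interval -0.16 to 1.29), FOS at 0.43 (interval -0.39 to 1.25), the early response gene CCN1 at 0.74 (interval 0.10 to 1.37) and GARIN4 at 0.97 (interval -2.01 to 3.95). The adhesion gene CHL1 (-1.95, SE 0.69) and the Wnt and BMP antagonist gene SOSTDC1 (-2.44, SE 0.87) were among those with the smallest p on the lower side. The edgeR quasi-likelihood test called 0 of 23231 genes (78 at an unadjusted p under 0.05), as did DESeq2, limma voom with quality weights and the codes, and DESeq2 with the codes, and 90.9% of the 11980 genes had their interval within 1 log2 unit of 0. The ribosomal list turned to a mean of 0.15 without Morphine 3 (adjusted p = 0.132) and 0.16 without beta-endorphin 2 (0.00731), and ended without Control 3 (0.0523) or beta-endorphin 1 (0.0721). The cell cycle list turned to -0.06 without beta-endorphin 1 (0.479) and ended without Morphine 2 (0.888) or beta-endorphin 3 (0.162), while the mitochondrial call ended without beta-endorphin 1 (0.176). Within codes A, B and C the differences were -0.67, -0.00 and -0.42 for the mitochondrial list, 0.31, -0.08 and 0.07 for the cell cycle and 0.18, -0.67 and 0.03 for ribosomal proteins.

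Naloxone and morphine share the morphinan skeleton. Naloxone carries an allyl group on the nitrogen where morphine has a methyl group, and further changes on the ring system. At 200 and 193 nM, the title genes were higher with naloxone than with morphine (3 of 3, median 2.84; adjusted p = 9.43e-07, and adjusted p = 0.0134 with an estimated correlation), although 0 of 3 passed adjusted over the list alone. As the study chose these genes on these samples, this call is not independent evidence. GARIN4 stood at 2.84 (interval 0.26 to 5.42), TRIM56 at 2.96 (interval 0.12 to 5.80) and RASAL1 at 2.00 (interval -0.68 to 4.68), with 17 reads of GARIN4 in the 3 naloxone libraries together. Mitochondrially encoded mRNAs were lower with naloxone (13 of 13, median -0.23; adjusted p = 0.000751, and adjusted p = 0.993 with an estimated correlation). FOS differed by 0.54 (interval -0.28 to 1.36) and EGR1 by 0.29 (interval -0.44 to 1.01). PALMD (1.57, SE 0.50) and XAGE1B (3.45, SE 1.25) were higher and LINC01252 (-0.95, SE 0.32) lower among those with the smallest p. The value for XAGE1B rests on Naloxone 1, which held 531 of its 566 reads in naloxone, and without that library it was 0.12. The edgeR quasi-likelihood test called 0 of 23231 genes (81 at an unadjusted p under 0.05), DESeq2 0, limma voom with quality weights and the codes 0, and DESeq2 with the codes 1, HCG4, which had no reads in naloxone. In this comparison 92.1% of the 11980 genes had their interval within 1 log2 unit of 0. The title call held with each library left out, but without Control 1, Naloxone 1 and Naloxone 2 together, where 1 naloxone library remains, the mean was 0.30 (adjusted p = 0.35). The mitochondrial list turned to 0.09 without Naloxone 3 (adjusted p = 0.581). Within codes A, B and C the differences were 0.10, 0.05 and -1.21 for this list and 1.63, 1.63 and 0.57 for the title genes.

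Beyond single compounds, 3 wider tests asked whether any group differed, whether the compounds as a whole differed from water, and whether the antagonist differed from the other 4 compounds. In the mean of the 5 compounds GARIN4 stood at -3.87 (SE 0.67, adjusted p = 0.214), MYO1F at -2.24 (SE 0.41, adjusted p = 0.223), TRIM56 at -3.67 (SE 0.71) and the calcium channel gene CACNA1A at -5.19 (SE 1.02, adjusted p = 0.297). The value for CACNA1A rests on Control 1, which held 276 of its 277 reads in Control, and without that library it was 2.09. On the higher side RNU6-146P stood at 1.78, ITGA6 at 1.08 (SE 0.24) and CNTN1 at 0.74 (SE 0.17). Naloxone against the other 4 had the smallest p for XAGE1B (3.72, SE 0.79), FZD10-AS1 (1.57, SE 0.47) and GARIN4 (2.65, SE 0.82) on the higher side and for RGPD5 (-1.23, SE 0.41) and LINC01252 (-0.80, SE 0.27) on the lower. Without Naloxone 1, XAGE1B stood at 0.38. The edgeR quasi-likelihood test called 0 genes in each (565 at an unadjusted p under 0.05 among the 6 groups, 2654 for the mean of 5 and 85 for naloxone against 4). DESeq2 called 9, 12 and 0, limma voom with quality weights and the codes 0, 11 and 0, and DESeq2 with the codes 36, 943 and 1. In the simulated counts for morphine, DESeq2 with the codes made 58 and 69 false calls in the 2 settings of spread. Part of its calls here may therefore be false. Among the 9 of DESeq2 were GARIN4 (adjusted p = 0.0341), RGPD5 (0.0279), MYO1F (0.0341) and LSR (0.0314), and the 12 included ITGA6 and CNTN1 on the higher side. For the mean of the 5 compounds, edgeR called 123 genes without Control 3, of which 111 were lower, and 3270 without the low-count filter, of which 3244 were lower. The fit without the filter took in all 46594 genes with at least 1 count. Control 1 held 20888 reads in protein-coding genes with a median count of 0. Whether the calls of that fit rest on Control 1 was not tested.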

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

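The fits without Control 1, Naloxone 1 and Naloxone 2, those that combine left-out libraries with the code, DESeq2 with the code and limma voom with quality weights and the code were chosen after the results were seen; the other alternatives were not. RLE scaling, the fits of the compared groups alone and the replicate number as a block kept all gene counts at 0. With 1 library left out, gene counts stayed at 0 in each comparison but the mean of 5 compounds. Counts of changed genes moved from 0 as follows. DESeq2 gave 1 for TRV130, beta-endorphin and naloxone, 9 among the 6 groups and 12 for the mean of 5 compounds. DESeq2 with the code gave 2 for morphine, 4 for TRV130, 14 for beta-endorphin, 1 for naloxone against morphine and against the other 4, 36 among the 6 groups and 943 for the mean of 5. That fit also made the most false calls in the simulated counts. Limma voom with quality weights and the code gave 1 for TRV130, 22 for beta-endorphin and 11 for the mean of 5. For the mean of 5, edgeR gave 3270 without the low-count filter (3244 lower), between 0 and 123 with 1 library left out (123 without Control 3), and 1 with Control 1 left out and the code in the model. List calls against Control, 37 in all libraries, numbered 36 with RLE, 58 without the low-count filter, between 25 (without Control 2) and 54 (without Control 1) with 1 library left out, 62 without Control 1, Naloxone 1 and Naloxone 2, 43 without Control 1 and 38 without those 3 with the code, 2 with an estimated correlation and 0 with fry. The cause was not tested.

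Reversed lists, as means on the log2 scale, were these. For TRV130 the epithelial list ran from -0.891 (without Control 3) to -0.0442 (without Control 1) with 1 library left out, and had -0.0255 without the 3 libraries, -0.00211 without Control 1 with the code and 0.083 without the 3 with the code. Without Control 1 and in those 3 settings, its direction relative to other genes turned. The last 2 also turned the TRV130 ribosomal list (0.155 and 0.132), respiratory chain (0.136 and 0.112) and histones (0.0651 and 0.0775). For naloxone without the 3 libraries, the ribosomal list had 0.386 and the respiratory chain 0.331, the latter 0.00628 with the code. There a single naloxone library of code C stands against Controls of codes B and C, and within code C it lay below Control (-0.125 and -0.0961), so this turn is no evidence of a rise. Against morphine with 1 library left out, the ribosomal list of beta-endorphin ran from -0.446 (without beta-endorphin 3) over 0.154 (without Morphine 3) to 0.164 (without beta-endorphin 2). Its cell cycle list ran from -0.055 (without beta-endorphin 1) to 0.298 (without beta-endorphin 2), and the mitochondrial list of naloxone from -0.43 (without Naloxone 2) to 0.0897 (without Naloxone 3). The cause was not tested.

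The libraries share only a number or a code. In most column names the code carries further digits and has the form of a date that the groups share, but the labels do not say what it marks or tie it to a shared culture. To look for pairing, the mean log2 CPM of its group was subtracted from each library, gene by gene. Between groups, these deviations correlated above 0.1 in 29 of 45 pairs of equal replicate number (median 0.335, from -0.56 to 0.759). For pairs of equal code they did so in 34 of 40 (median 0.459, from -0.411 to 0.759). The 2 TRV130 libraries of code A were averaged for this. With the replicate number as a block, edgeR called 0 genes in each comparison and 37 lists; with the code as a block, 0 genes in each except 1 for the mean of 5, and 37 lists. By compound the code block gave 8 lists against Control for morphine, 7 for metamorphine, 9 for TRV130, 8 for beta-endorphin and 5 for naloxone, where 7, 6, 11, 8 and 5 passed without it. Against morphine the code block gave 18 lists, where 9 passed without it. These were 2 for metamorphine, 6 for TRV130, 4 for beta-endorphin and 6 for naloxone, where 1, 3, 3 and 2 passed without it. With the code as a block and an estimated correlation, 0 lists passed against Control and 0 against morphine, where 2 and 1 passed without the block. The adjusted p of the title genes in that setting was 0.3 for morphine and for TRV130 against Control and 0.182 for naloxone against morphine.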

Other observations

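The gene and library size tests of the library codes, those of the top genes and the Control libraries behind the excess reads, of Control 1 and the within-code direction of the ribosomal and respiratory chain lists, and all other splits of the samples were chosen after the results were seen. The exon ratio and the 2 corrections for GC content and length were written before. With the code in the edgeR model, libraries of code B differed from those of code A in 2662 genes that were higher and 3594 that were lower, and code C from A in 3746 and 3963. For lists set against the code, the counts given are of members that passed on their own. Sterol synthesis genes were lower in both: 19 of 22 passed in code B (median -0.70; camera adjusted p = 0.011 with an estimated correlation) and 18 of 22 in code C (median -0.52; adjusted p = 0.0243 with an estimated correlation). In code C the sterol enzyme gene DHCR7 stood at -1.32 (SE 0.10) against code A, the fatty acid synthase gene FASN at -1.56 (SE 0.13), and TNC, an extracellular matrix glycoprotein, at -2.16 (SE 0.14). Replication-dependent histones were higher there, with 12 of 22 passing on their own and a median of 0.81 over the list (adjusted p = 0.0356 with an estimated correlation; H2BC8 1.47, SE 0.15), and the antiproliferative gene BTG2 stood at 0.99 (SE 0.09).

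Code B stood below code A in the chemokine receptor gene CXCR4 (-1.46, SE 0.14), MYC (-1.23, SE 0.14) and the growth cone gene GAP43 (-1.02, SE 0.10), and above it in ANGPTL4 (1.76, SE 0.17), a lipoprotein lipase inhibitor. Of the cell cycle list, 27 of 34 genes passed on their own as lower in code B (median -0.56; adjusted p = 0.203 with an estimated correlation).

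The differences between codes could reflect how the libraries were made or the state of the cells, and the labels give no factor with which to tell these apart, so no biological explanation was tested. A GC content or gene length trend is argued against as the whole cause of the sterol difference between codes C and A. Relative to all genes, the sterol median between these codes was -0.50 before the trend was removed and -0.62 after. Over 23200 genes the difference between codes C and A did correlate with GC content (Spearman -0.322), and little with exon length (0.0119). Such a trend therefore stays open for other genes. Library size is argued against as well, since 4 of 5 libraries of code C lay inside the range of totals of the other codes.

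Control 1 held 20888 reads of genes near 0 in most other libraries, and a candidate explanation is a background that covers genes by length, such as genomic DNA. Among these genes, those with 1 exon had 0.644 times the reads per kb of genes with several exons at like GC content (95% interval 0.534 to 0.766), above the bound of 0.5 set beforehand, but below 1 and below the ratio in each of the 17 other libraries. The next lowest ratios were those of Naloxone 1 (0.705) and Naloxone 2 (0.769). RNA of a single other cell type is argued against, since the 10 genes with the most reads held 4.94% of them, and so is a response to water, since 1 of 3 Control libraries lay above all 15 compound libraries. In Control 1 the reads per kb of CACNA1F, TRIM56 and RASAL1 lay at percentiles 96.4, 90.8 and 85.8 of such genes of like GC content, and those of GARIN4 at 61.6. In Control 2 the percentiles were 90.0 for CACNA1F, 96.2 for TRIM56, 97.5 for RASAL1 and 99.8 for GARIN4, and in Control 3 they were 95.1 for RASAL1 and 99.8 for GARIN4, with 0 reads of CACNA1F and TRIM56. Only 403 of 3587 such genes had any read in Control 2 and 184 in Control 3, so a few reads give a high percentile there. That of RASAL1 in Control 3 rests on 1 read and that of CACNA1F in Control 2 on 4 reads.

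Ribosomal protein and respiratory chain mRNAs lay below other genes in all 5 compounds, in 10 of 10 tests with camera at its preset correlation. None of these passed with an estimated correlation (adjusted p from 0.886 to 0.914) or with fry. A GC content or length trend is argued against as the whole cause, since 10 of 10 tests passed after it was removed from each library. With camera on log2 CPM, this correction ended the epithelial calls of morphine (adjusted p 0.0262 before, 0.161 after), metamorphine (0.00452, 0.0573), beta-endorphin (0.0104, 0.094) and naloxone (0.0143, 0.0963). It also ended the TRV130 glial call (0.0336, 0.0611) and the beta-endorphin Ras GTPase-activating call (0.0398, 0.094), while other lists passed only after it. For the ribosomal and respiratory chain lists, Control 1 alone stays open as a cause, since 5 of 10 tests passed without it. A response to the compounds also stays open: within codes B and C, the ribosomal and respiratory chain lists lay below the Control library of the same code in 14 of 18 comparisons, short of the 16 set for it. These comparisons are not independent, since each code has a single Control library and both lists had the same sign in each compound. In code C both lay below Control in every compound, and in code B they lay above it in morphine and metamorphine.

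The groups were also compared with other splits of the same samples. For each of the 9 comparisons of 3 libraries with 3, there are 10 splits, too few for a share under 0.05, and the real one called 0 genes in each. The highest count among the other splits was 0 in 7 of them, 1393 for TRV130 and Control and 3937 for naloxone and Control. The split with 1393 sets Control 1 with TRV130 1 and 2, the libraries of code A, against the rest, and that with 3937 sets Control 1, Control 3 and Naloxone 3 against the rest, which points to a structure of the samples other than the compounds. Over 40 splits drawn for each wider test, the real count was 0 among the 6 groups (highest other 4547), for the mean of 5 compounds (highest other 2794) and for naloxone against the other 4 (highest other 0). A real count of 0 fixes the outcome, 40 of 40 splits with at least as many, so these splits say nothing about chance. For the gene lists, 20 of 40 splits gave at least the 37 real calls (highest other 54). The drawn splits did not keep the library codes balanced over the groups, as the real groups nearly do, so their calls also carry differences between codes. They do not exclude chance for the number of list calls and give no rate for it.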
